A study of Homo sapiens with 8 samples.

How the data were processed

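Total RNA of 8 SK-N-AS xenograft tumours, 4 from vehicle mice and 4 from mice treated with h10H5, was labelled with biotin from 3 µg per sample, per the labels' protocols, and hybridised to Affymetrix arrays, whose model is not given in the sources used here. The labels call the vehicle tumours biological replicates and the h10H5 tumours replicates only. The deposited table holds 1 signal intensity per probe set and array on a linear scale. The software that summarised the probes, its background correction and its detection calls are not given in the sources used here. In the deposited intensities the mean without the lowest and highest 2% of probe sets was the same on all 8 arrays (499.9), so each array appears scaled by 1 factor to a common trimmed mean, and no further scaling was applied because array medians differed by 0.36 on the log2 scale, under the limit of 0.5 set beforehand for normalizing again. A change that lowers many strong signals can raise weaker ones under such scaling, so a median-centred and a quantile normalized version were run as alternatives.

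Probe sets were named through GEO's platform annotation. 41097 named exactly 1 gene, 1801 several and 11777 none. Symbols of 41043 of the first kind were updated through their gene number with NCBI RefSeq's gene table for GRCh38.p14, and 54 were not found there and kept the platform's symbol; since the build behind the array's design is not given in the sources used here, no coordinates are given. Values under 12.1, the 10th percentile of the table, were raised to it, log2 was taken, and the 62 control probe sets were left out. Only probe sets with a mean log2 signal above the median of all (6.95) were tested. For each gene the probe set with the highest mean signal was kept, which left 12330 genes from 27288 probe sets; 4544 of the tested probe sets name no single gene, and 34 of these were higher and 23 lower in h10H5 tumours. Fits used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, two-sided) on all 8 arrays with the group as the term, and Benjamini-Hochberg adjusted p under 0.05 as the threshold. Every call and adjusted p of a gene comes from this limma fit. In simulated data with 200 changed genes among 12330, for the same comparison and spread per gene, genes were drawn independently of each other and without array effects. There 28% of genes changed by 0.5 log2 units were recovered, 80% at 1, 94% at 1.5 and 100% at 2. In that simulation 7 unchanged genes were called, and 0 genes were called where nothing was changed. These rates need not hold for the real arrays, where genes move together.

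22 gene lists and 9 lists of markers of other cell types were written before the data were examined, and the 26 with at least 5 tested members were tested with camera from limma at its preset correlation of 0.01, with the correlation estimated from the data, and with fry, which asks only whether a list's own genes move on balance one way. By camera 3 lists shifted up and 9 down. With an estimated correlation 0 of the 26 passed after adjustment and 5 had an unadjusted camera p under 0.05. Fry's directional test called 10, all of them also called by camera. Fry's mixed test asks instead whether a list's own genes change in either direction. Of the lists camera did not call, it called the IGF axis, hypoxia, heat shock, apoptosis, p53, lysosome, noradrenergic and fibroblast lists (adjusted p from 9.82e-07 to 0.0139). It did not call the mitochondrial, cytosolic ribosomal, interferon, mesenchymal, endothelial and myeloid lists (0.068 to 0.726). The adjusted p of each of these lists covers the 26 lists; for 6 lists written after the values were seen it covers 32 lists, these 6 and the 26. Genes were named by a rule also fixed beforehand: IGF1R, IGF1, IGF2, INSR, IRS1, IRS2, ACTB and GAPDH in any case; the 12 largest increases and 12 largest decreases among genes past the threshold whose group values do not overlap; and per list up to 4 members past the threshold with the largest differences, or, where none passed, the 2 with the highest mean. Alternatives were quantile normalization, median centring, log2 of the value plus 16 without a floor, no filter and a stricter filter (75th percentile) on dim probe sets, eBayes with trend and robust settings, array weights, a term for the replicate number, leaving out each array, the mean of a gene's probe sets, and leaving out probe sets whose names end in _s_at, _x_at or _a_at, which mark probes shared between transcripts.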

Results

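Expression was measured in tumours of SK-N-AS, an established human neuroblastoma line, grown under the skin of nude mice. 4 tumours came from mice given vehicle. The other 4 came from mice given h10H5, an antibody against the insulin-like growth factor receptor encoded by IGF1R, at 5 mg/kg into the peritoneum, and carry a time of 24 hours; the labels of the vehicle tumours carry no time. Each tumour was hybridised to 1 Affymetrix array whose probe sets target human transcripts. Median log2 signals of the arrays lay between 6.96 and 7.32, and h10H5 replicates 2 and 4 were the highest at 7.32 and 7.21. The ratio of the 3' to the 5' ACTB control probe sets, which rises as RNA is shortened, was 1.81 in h10H5 replicate 4 and between 1.11 and 1.45 on the other 7 arrays. The same ratio for GAPDH did not set that array apart (1.05, against 0.987 to 1.10 on the others). With 4 arrays per group, their number limits the precision of each difference. All differences below are h10H5 minus vehicle on the log2 scale, with the standard error from limma.

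The comparison asks which transcripts differ in the tumours a day after the antibody. Of 32 DNA replication genes 31 fell in the h10H5 tumours. So did 7 of 30 mitosis genes, 7 of 18 of cholesterol and 5 of 15 of fatty acid synthesis (1 rose), 3 of 22 of glycolysis and 4 of 25 of the amino acid response. Of 23 genes induced by FOXO transcription factors 6 rose, among them KLHL24, PNRC1 and YPEL3. These 7 lists passed camera at its preset correlation and not with an estimated correlation (adjusted p = 0.0651 for the replication, FOXO and amino acid lists, 0.103 for mitosis and cholesterol, 0.35 for fatty acids and glycolysis). Except for the replication and amino acid lists, these counts moved by more than 1.5 times without single arrays, as given with each list. The list of housekeeping controls also passed camera at its preset correlation (mean −0.24, camera adjusted p = 0.00309). The downward means of the mitosis, fatty acid and amino acid lists were of about that size. Their means alone therefore do not set them apart from the controls, and no test compared these lists with them. The transcript of the targeted receptor did not pass the test. Of 12330 genes tested, 340 were higher and 478 lower in the h10H5 tumours, which is 6.63% of all. At least 1.5-fold differences were found for 162 higher and 275 lower genes, and at least 2-fold differences for 22 higher and 72 lower genes. In 813 of the 818 changed genes no h10H5 value lay within the range of the vehicle values. The calls rest on the same values, so this is no separate support for them. By chance alone the groups would separate in 2.86% of genes. Counted by probe set, 261 were higher and 399 lower among 27288.

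The balance of directions moved with median centring of the arrays. As deposited, 58.4% of the changed genes were lower, and with quantile normalization 60.7% (345 higher and 532 lower). Centring gave 89.9% (51 higher and 452 lower) and moved the median difference of all genes from 0.02 to −0.12. The counts also fell when single arrays were left out, to 94 higher and 184 lower without vehicle replicate 4, 99 and 183 without vehicle replicate 1, 213 higher without vehicle replicate 2, 162 and 248 without vehicle replicate 3, 148 and 283 without h10H5 replicate 1, and 178 and 305 without h10H5 replicate 3. The counts of at least 1.5-fold differences fell to 89 and 167 without vehicle replicate 1 and 79 and 174 without vehicle replicate 4. Those by probe set fell to 31 and 90 without vehicle replicate 1 and likewise without vehicle replicate 4, 92 and 241 without vehicle replicate 2, and 72 and 153 without vehicle replicate 3. They were 54 and 176, 112 and 221, and 66 and 166 without h10H5 replicates 1, 2 and 3. With dim probe sets included, 41 of the 66 named genes past the threshold still passed. Those that did not, with adjusted p from 0.0510 to 0.120, were ACACA, ALLC, ATG14, BIRC5, BUB1B, CCNG2, CDC45, CENPM, CRYAB, CSPG4, E2F2, ENO2, GADD45A, GLA, IDI1, MXI1, MYCN, OSER1-DT, PFKFB3, PGAM1, PLCD1, PNRC1, PSAT1, SPRY1 and WIPI1.

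Of the 12 genes with the largest decreases 5 (CCNE2, CDC45, CDC6, E2F2 and RRM2) stand on the replication list. CENPM, a centromere protein, fell by 2.18 ± 0.49 (SE; 8.84 ± 0.26 in vehicle and 6.65 ± 1.18 in h10H5 tumours, SD, n = 4 each; adjusted p = 0.0332). TEDC2 fell by 1.90 ± 0.18, CDC45, a part of the replicative helicase, by 1.82 ± 0.38, and CCNE2, the cyclin E2 that drives entry into S phase, by 1.81 ± 0.16. The helicase loader CDC6, the phosphatase CDC25A, the ribonucleotide reductase subunit RRM2, the ubiquitin ligase adaptor DTL, CHAC2, the transcription factors E2F2 and E2F7, and TEX15 followed, with differences between −1.75 and −1.47. RRM2 was 12.51 ± 0.14 in vehicle and 10.85 ± 0.12 in h10H5 tumours (SD, n = 4 each; 3.14-fold lower; adjusted p = 3.39e-04). E2F7 was 10.45 ± 0.12 and 8.98 ± 0.05 (SD, n = 4 each; 2.77-fold lower; adjusted p = 3.39e-04). In h10H5 replicate 4 CENPM was 5.00, against 6.89 to 7.79 on the other h10H5 arrays, and CDC45 was 6.66, against 8.12 to 8.62. The sizes of these decreases, and so their ranks, rest in part on that array. The call of CENPM ended when any array other than h10H5 replicates 3 and 4 was left out (adjusted p up to 0.0898). That of E2F2 ended for any other than h10H5 replicates 2 and 4 (up to 0.0865), and that of CDC45 without vehicle replicate 1, 3 or 4 or h10H5 replicate 1 (up to 0.0778). TEX15 had 1 other tested probe set, which lay the other way with no call.

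**Figure D1:**
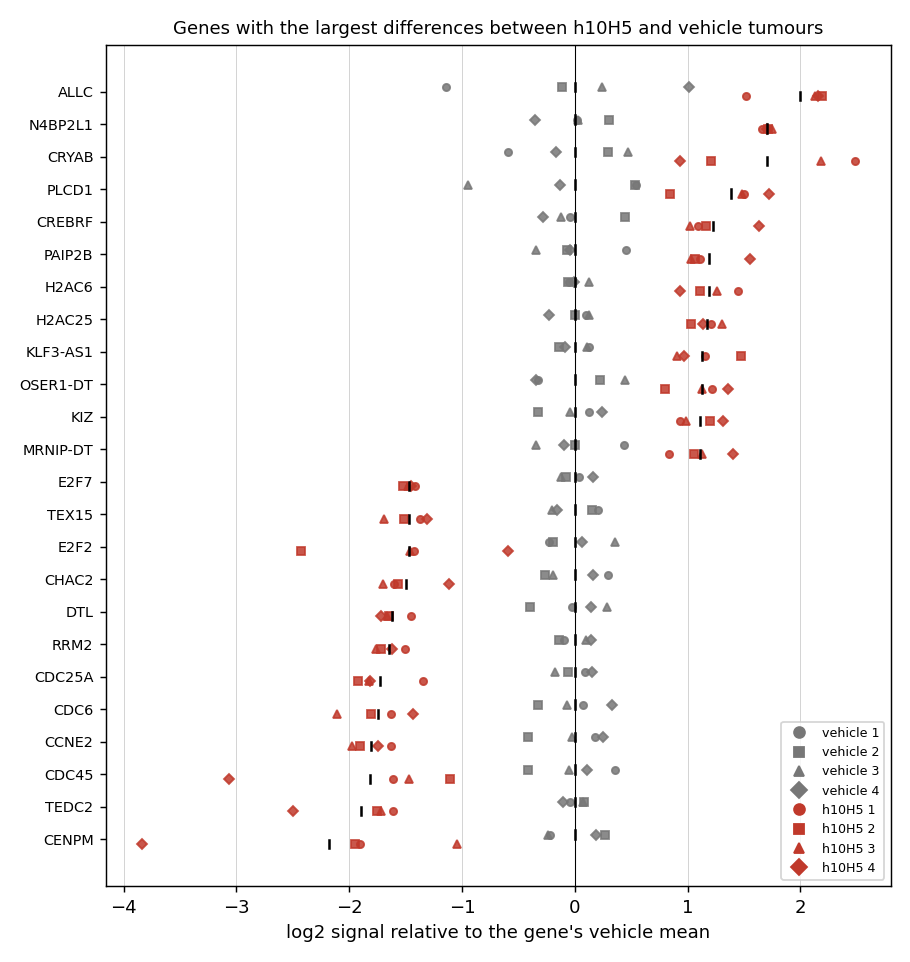
log2 signal of the 12 genes with the largest increases and the 12 with the largest decreases on each array, relative to the gene's vehicle mean; grey symbols are vehicle tumours, red symbols are h10H5 tumours, the symbol shape gives the replicate, and black bars are means of 4. No h10H5 value overlaps the vehicle values, as the rule that chose these genes required, and h10H5 replicate 4 lies lowest for CENPM, TEDC2 and CDC45.

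Of the 12 genes with the largest increases 1, CRYAB, stands on a fixed list, that of heat shock proteins. ALLC, an allantoicase homologue, was 6.14 ± 0.90 in vehicle and 8.14 ± 0.32 in h10H5 tumours (SD, n = 4 each), a rise of 2.00 ± 0.39 (SE; adjusted p = 0.0205). N4BP2L1 rose by 1.70 ± 0.13 (3.26-fold; adjusted p = 8.16e-04), from 7.25 ± 0.27 to 8.95 ± 0.04 (SD, n = 4 each). That value comes from a probe set whose name marks shared probes. Without such probe sets the difference of N4BP2L1 was 0.13 (adjusted p = 0.718), while the mean of its probe sets gave 0.95 (adjusted p = 0.00101). Of its 3 other tested probe sets 0 lay the other way, and 1 passed as higher in the fit over all probe sets. CRYAB, a small heat shock protein abundant in muscle, rose by 1.70 ± 0.37. PLCD1, CREBRF, PAIP2B, the histone genes H2AC6 and H2AC25, the noncoding transcripts KLF3-AS1, OSER1-DT and MRNIP-DT, and KIZ rose by between 1.11 and 1.39. The call of ALLC ended without h10H5 replicate 3 (adjusted p = 0.0515) and that of CRYAB without vehicle replicate 1 or 4 or h10H5 replicate 1 or 3 (up to 0.0829). That of PLCD1 ended with arrays centred on their medians (1.25, adjusted p = 0.0517), with quantile normalization (1.26, adjusted p = 0.0629) and when any array other than vehicle replicate 2 and h10H5 replicate 2 was left out (up to 0.102).

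In the receptor's own pathway no gene passed the test. IGF1R was 11.98 ± 0.19 in vehicle and 11.90 ± 0.26 in h10H5 tumours (SD, n = 4 each), a difference of −0.08 with a 95% interval from −0.42 to 0.26 (adjusted p = 0.783). Its 3 other tested probe sets lay the other way, at 0.28, 0.30 and 0.85, and none passed the test over all probe sets, though the 1 at 0.85 had an unadjusted limma p under 0.05 (adjusted p = 0.133). The insulin receptor INSR differed by 0.25 ± 0.18 (adjusted p = 0.426), and of the adaptors that carry the receptors' signal, IRS1 differed by −0.11 ± 0.22 (adjusted p = 0.799) and IRS2 by 0.41 ± 0.12 (adjusted p = 0.0705). IRS2 passed under several other settings, among them quantile normalization (0.47, adjusted p = 0.0208) and leaving out h10H5 replicate 4 (0.50, adjusted p = 0.0282). Of the list of 20 measured receptors, ligands, binding proteins and adaptors, 0 rose and 0 fell, also when adjusted over the list alone, with SHC1 at 0.19 (0.39 and adjusted p = 0.048 with the mean of its probe sets) and IGFBP2 at −0.14. The list did not shift 1 way as a whole (mean 0.02, camera adjusted p = 0.867). Fry's mixed test, which asks whether members change in either direction, did pass (adjusted p = 3.03e-04), though no member passed alone. The housekeeping controls gave the same adjusted p in that mixed test, so it does not set the IGF list apart from them. IGF1 was below the limit for dim signals, and IGF2 shares its probe sets with another gene, so neither was tested.

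Replication genes showed the clearest group change. Of 32 measured genes of the G1/S transition and DNA replication, 31 fell and 1 did not pass (all 32 fell when adjusted over the list alone). The mean difference was −1.11, and list means of the h10H5 arrays ran from −1.15 to −1.01 relative to vehicle. The exception, looked up after the values were seen, was the primase gene PRIM1 at −0.26 (adjusted p = 0.182). CDC45, CCNE2, CDC6 and RRM2 had the largest decreases, given above. The shift passed camera (adjusted p = 5.46e-35) but not with an estimated correlation (adjusted p = 0.0651).

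Of 30 mitosis genes 7 fell (15 when adjusted over the list alone) and 23 did not pass. CDK1, the mitotic kinase, fell by 0.68 ± 0.09 (adjusted p = 0.00432), BIRC5, the survivin of the chromosomal passenger complex, by 0.66 ± 0.13, the checkpoint kinase BUB1B by 0.61 ± 0.12 and the spindle motor KIF11 by 0.53 ± 0.09. The list's mean was −0.28 (camera adjusted p = 2.09e-07; adjusted p = 0.103 with an estimated correlation). The calls of BIRC5, BUB1B and KIF11 each ended without vehicle replicate 1 or 4 (adjusted p up to 0.0643, 0.069 and 0.0563), and those of BIRC5 and BUB1B also without vehicle replicate 3. Of the list 1 gene fell without vehicle replicate 1 or 4, 2 without vehicle replicate 3, 4 without h10H5 replicate 3 or with dim probe sets included, and 12 with array weights. Of the 3 other tested probe sets of BIRC5, 1 lay the other way with no call, and the mean of its probe sets did not pass (−0.32, adjusted p = 0.0781).

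Of 18 genes of cholesterol synthesis 7 fell (10 fell and 1 rose when adjusted over the list alone) and 11 did not pass. FDPS, farnesyl diphosphate synthase, fell by 1.05 ± 0.13, from 12.47 ± 0.26 to 11.43 ± 0.04 (SD, n = 4 each; adjusted p = 0.00327). ACAT2 fell by 0.93 ± 0.13, DHCR7, the last enzyme of a branch of the pathway, by 0.93 ± 0.12, and the isomerase gene IDI1 by 0.76 ± 0.16. The list's mean was −0.46 (camera adjusted p = 7.57e-07; adjusted p = 0.103 with an estimated correlation). IDI1 changed sign, to 0.24 (adjusted p = 0.539), when probe sets whose names mark shared probes were left out. Of its 3 other tested probe sets 2 lay the other way, the mean of its probe sets did not pass (−0.27, adjusted p = 0.227), and its call ended without any array other than vehicle replicate 2 and h10H5 replicate 4 (adjusted p up to 0.0773). Without vehicle replicate 3 or 4 another probe set of DHCR7 had the highest mean and stood for the gene, and it did not pass (−0.43 and −0.34; adjusted p = 0.181 and 0.335). The usual probe set differed there by −0.87 and −0.92. Of the list 4 genes fell without vehicle replicate 1 or h10H5 replicate 2 or with dim probe sets included, 3 without vehicle replicate 3 and 2 without vehicle replicate 4.

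Of 15 fatty acid synthesis genes 5 fell, 1 rose and 9 did not pass (7 fell and 1 rose when adjusted over the list alone). The desaturase FADS2 fell by 0.95 ± 0.16, fatty acid synthase FASN by 0.62 ± 0.10 (adjusted p = 0.00898), the elongase ELOVL6 by 0.59 ± 0.10, and ACACA, which makes malonyl-CoA, by 0.58 ± 0.13. The gene that rose, looked up after the values were seen, was ACSS2, an acetyl-CoA synthetase, at 0.53 ± 0.13 (adjusted p = 0.0435). The mean was −0.22 (camera adjusted p = 0.00626; adjusted p = 0.35 with an estimated correlation). The call of ACACA ended without any array other than h10H5 replicate 4 (adjusted p up to 0.0988), its 1 other tested probe set lay the other way with no call, and the mean of both did not pass (−0.28, adjusted p = 0.265). That of ELOVL6 ended without vehicle replicate 1 (0.0518). Of the list 2 genes fell without vehicle replicate 1, and 3 without vehicle replicate 3 or 4 or h10H5 replicate 3 or with dim probe sets included. 0 rose with centring, with dim probe sets included or without any array other than vehicle replicate 1.

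Of 22 genes of glycolysis and glucose uptake 3 fell (8 when adjusted over the list alone) and 19 did not pass. ENO2, the neuronal enolase, fell by 0.80 ± 0.15, the mutase gene PGAM1 by 0.56 ± 0.12, and PFKFB3, which makes an activator of phosphofructokinase, by 0.55 ± 0.12. The list's mean was −0.39 (camera adjusted p = 5.23e-06; adjusted p = 0.35 with an estimated correlation), with vehicle replicate 3 highest at 0.31 and h10H5 replicate 4 lowest at −0.55. The call of ENO2 ended without vehicle replicate 1 or 3 or h10H5 replicate 1 (adjusted p up to 0.0635). That of PGAM1 ended without any array other than h10H5 replicates 3 and 4 (up to 0.0747), and that of PFKFB3 without any other than vehicle replicate 4 and h10H5 replicate 4 (up to 0.0858). Of the list 0 genes fell without vehicle replicate 1 or 3 or h10H5 replicate 1 or with dim probe sets included, 1 without vehicle replicate 2 or h10H5 replicate 2, and 6 with quantile normalization. The hypoxia list, which has no gene in common with the glycolysis list, did not pass (mean −0.21, camera adjusted p = 0.139). Of its 21 genes 1 was higher and 1 lower (1 higher and 3 lower when adjusted over the list alone). MXI1, an antagonist of MYC, rose by 0.57 ± 0.13 and the lipid droplet gene HILPDA fell by 0.41 ± 0.08. The list passed without vehicle replicate 4 (−0.32, adjusted p = 0.0128), without h10H5 replicate 1 (−0.29, adjusted p = 0.0468) and with dim probe sets included (−0.28, adjusted p = 0.0435), but shrank to −0.07 without vehicle replicate 3 (adjusted p = 0.626). MXI1 and HILPDA did not pass with arrays centred on their medians (0.44 and −0.55; adjusted p = 0.17 and 0.055) or without 6 of the 8 arrays in turn (up to 0.101 and 0.0823).

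Of 25 genes of the ATF4 amino acid response 4 fell (9 when adjusted over the list alone) and 21 did not pass. The amino acid transporters SLC7A5 and SLC7A1 fell by 0.75 ± 0.11 and 0.56 ± 0.10, the mitochondrial folate enzyme MTHFD2 by 0.72 ± 0.10 (adjusted p = 0.00574), and PSAT1, of serine synthesis, by 0.53 ± 0.11. The mean was −0.28 (camera adjusted p = 3.46e-05; adjusted p = 0.0651 with an estimated correlation). Among 23 ribosome biogenesis genes 1 fell and 22 did not pass, the same counts as when adjusted over the list alone (2 fell without h10H5 replicate 3): NOP16, a nucleolar protein, fell by 0.45 ± 0.09. That list's mean was −0.20 (camera adjusted p = 0.00163; adjusted p = 0.35 with an estimated correlation). For 19 cytosolic ribosomal proteins 0 passed, also when adjusted over the list alone, RPS16 differed by −0.05 and RPS19 by −0.03, and the mean was −0.01 (camera adjusted p = 0.814). The call of PSAT1 ended without vehicle replicate 1, 2 or 4 (adjusted p up to 0.0743) and with the mean of its probe sets (−0.44, adjusted p = 0.0513). That of SLC7A1 ended with that mean (−0.55, adjusted p = 0.133) and without probe sets that mark shared probes (−0.61, adjusted p = 0.0567). That of NOP16 ended without vehicle replicate 1, 3 or 4 or h10H5 replicate 1 (up to 0.0643), with the mean of its probe sets (−0.34, adjusted p = 0.0592) and without probe sets that mark shared probes (−0.23, adjusted p = 0.299).

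No gene of the unfolded protein response of the endoplasmic reticulum passed among 19, also when adjusted over the list alone. The chaperone HSPA5 differed by −0.12 and SEC61B by −0.19, and the list's mean of −0.12 passed narrowly (camera adjusted p = 0.0458; adjusted p = 0.585 with an estimated correlation) and lost the call without vehicle replicate 1 or 4 or h10H5 replicate 2 or 4 (up to 0.122), with quantile normalization (adjusted p = 0.148), with arrays centred on their medians (adjusted p = 0.0629) and with a stricter filter (adjusted p = 0.136). Of 29 mitochondrial respiration genes 0 passed, also when adjusted over the list alone; the highest expressed, ATP5F1A and ATP5F1B, differed by 0.09 and 0.00, and the list's mean was −0.10 (camera adjusted p = 0.0994). That list passed without vehicle replicate 1 (adjusted p = 0.037), h10H5 replicate 1 (adjusted p = 0.0396) or h10H5 replicate 3 (−0.15, adjusted p = 0.0109) and with dim probe sets included (adjusted p = 0.0382), but shrank to −0.04 (adjusted p = 0.47) without h10H5 replicate 4.

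Of 23 measured FOXO-induced genes 6 rose (12 when adjusted over the list alone), 17 did not pass and 0 fell. KLHL24 rose by 1.05 ± 0.15 (10.41 ± 0.24 in vehicle and 11.46 ± 0.19 in h10H5 tumours, SD, n = 4 each; adjusted p = 0.00486), PNRC1 by 1.01 ± 0.18, YPEL3 by 0.90 ± 0.13 and CCNG2, a cyclin of resting cells, by 0.55 ± 0.13. The mean was 0.45 (camera adjusted p = 1.98e-07; adjusted p = 0.0651 with an estimated correlation), and h10H5 arrays lay between 0.41 and 0.50 against vehicle arrays between −0.08 and 0.12. The call of CCNG2 ended without any array other than h10H5 replicate 3 (adjusted p up to 0.087) and with arrays centred on their medians (0.42, adjusted p = 0.148). Of the list 3 genes rose without vehicle replicate 1 or 4 or h10H5 replicate 1 or with centring, 2 with dim probe sets included, where PNRC1 did not pass (adjusted p = 0.0510), and 13 with array weights.

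The list of ERK output and feedback genes moved in both directions. Of 19 genes 3 rose, 1 fell and 15 did not pass (6 rose and 1 fell when adjusted over the list alone). MYC rose by 0.73 ± 0.12 (adjusted p = 0.00956) and the feedback inhibitors of receptor signalling SPRY2 and SPRY1 by 0.53 ± 0.10 and 0.42 ± 0.10, while CCND1, cyclin D1, fell by 0.61 ± 0.11 (adjusted p = 0.0134). The mean of 0.17 passed narrowly (camera adjusted p = 0.0458; adjusted p = 0.35 with an estimated correlation) and not with arrays centred on their medians (0.04, adjusted p = 0.0637) or without vehicle replicate 1 or 4 or h10H5 replicate 1 or 3 (up to 0.111), nor without probe sets that mark shared probes (0.15, adjusted p = 0.16) or with dim ones included (0.09, adjusted p = 0.162). It did pass with quantile normalization (adjusted p = 0.00915). Centring also ended the calls of MYC (0.60, adjusted p = 0.0818), SPRY1 (0.29, adjusted p = 0.322) and SPRY2 (0.40, adjusted p = 0.158). Leaving out any 1 array ended that of SPRY1 (up to 0.104), as did the mean of its probe sets (0.38, adjusted p = 0.139), vehicle replicate 1 or 4 or h10H5 replicate 1 that of SPRY2 (up to 0.0649), and vehicle replicate 4 that of CCND1 (0.0512).

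**Figure D2:**
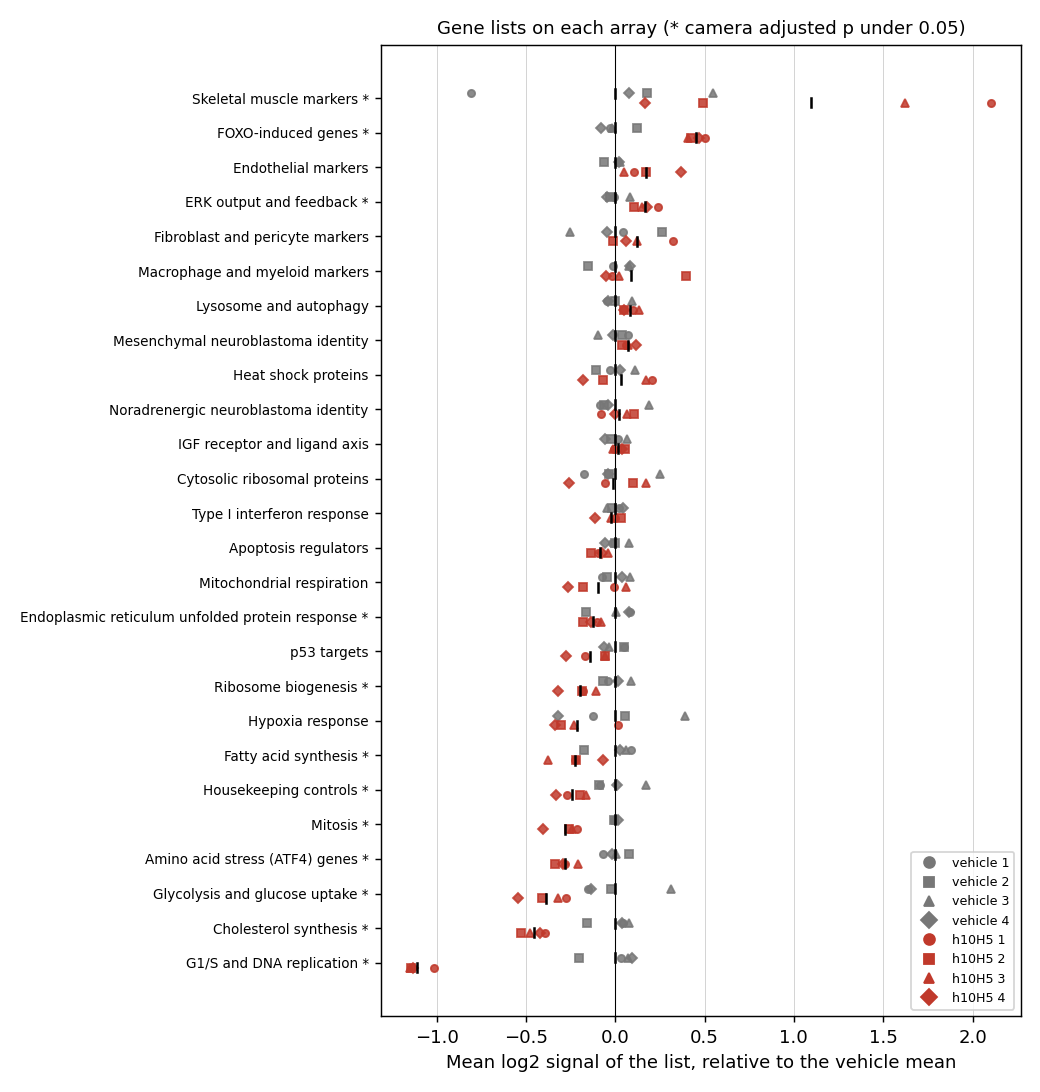
Mean log2 signal of each of the 26 tested lists on each array, relative to the vehicle mean; grey symbols are vehicle tumours, red symbols are h10H5 tumours, the symbol shape gives the replicate, black bars are means of 4, and an asterisk marks a camera adjusted p under 0.05. Replication genes lie near −1.11 in the h10H5 tumours and FOXO-induced genes near 0.45, while the skeletal muscle list is high on h10H5 replicates 1 and 3.

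The lists of apoptosis regulators, p53 targets and heat shock proteins did not pass camera as groups. Among 21 apoptosis regulators 1 rose, 1 fell and 19 did not pass, with the same counts when adjusted over the list alone. The BH3-only gene PMAIP1, which encodes NOXA, fell by 0.99 ± 0.13 (adjusted p = 0.00378), and BMF, another BH3-only gene, rose by 0.76 ± 0.13 (adjusted p = 0.0115); the list's mean was −0.09 (camera adjusted p = 0.398). Of 17 p53 targets 1 rose, also when adjusted over the list alone (2 without vehicle replicate 2): GADD45A, also on the FOXO list, at 0.55 ± 0.11, which did not pass with arrays centred on their medians (0.42, adjusted p = 0.172) or without vehicle replicate 1 or 4 or h10H5 replicate 1 or 3 (up to 0.0699). The other 16 did not pass and the list's mean was −0.14 (camera adjusted p = 0.238). Of 13 heat shock proteins 1 rose, also when adjusted over the list alone: CRYAB at 1.70 ± 0.37. Its signals of 10.1 and 9.79 in h10H5 replicates 1 and 3 lay above the 8.81 and 8.53 in replicates 2 and 4, and replicates 1 and 3 also had the highest signals of skeletal muscle genes. For this list the mean was 0.03, while the median of −0.07 and the direction of the test were downward (camera adjusted p = 0.607).

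Among 26 genes of lysosomes and autophagy 3 rose, 1 fell and 22 did not pass (4 rose and 1 fell when adjusted over the list alone; mean 0.08, camera adjusted p = 0.398). The protease CTSF rose by 0.92 ± 0.16 (adjusted p = 0.0136), the autophagy genes ATG14 and WIPI1 by 0.48 ± 0.10 and 0.43 ± 0.10, and GLA, the lysosomal galactosidase, fell by 0.42 ± 0.10. Of these 4 calls, that of CTSF held without each array in turn and with arrays centred on their medians. Those of ATG14, WIPI1 and GLA ended with centring (0.35, 0.30 and −0.56; adjusted p = 0.152, 0.267 and 0.0635) and without 5, 7 and 6 of the 8 arrays in turn (up to 0.0828, 0.118 and 0.104). That of WIPI1 also ended with quantile normalization and with trend and robust settings (adjusted p = 0.0682 and 0.0601). Of 21 interferon response genes 0 passed, also when adjusted over the list alone, with IFI44 at −0.17 and IFITM3 at 0.18 (mean −0.03, camera adjusted p = 0.707).

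The lists of neuroblastoma identity genes did not pass camera, though the noradrenergic list passed fry's mixed test (adjusted p = 1.74e-06). The housekeeping controls also passed that mixed test (adjusted p = 3.03e-04). Of 26 noradrenergic genes 1 rose, 1 fell and 24 did not pass, with the same counts when adjusted over the list alone and 2 higher without h10H5 replicate 4 (mean 0.02, camera adjusted p = 0.551). MYCN rose by 1.00 ± 0.19, from 7.59 ± 0.37 to 8.59 ± 0.20 (SD, n = 4 each; adjusted p = 0.0177), a call that ended without vehicle replicate 1 (adjusted p = 0.0518), and GAP43, a growth cone protein, fell by 0.61 ± 0.08 (adjusted p = 0.00447). Of 18 mesenchymal genes 0 passed, also when adjusted over the list alone, with VIM at 0.12 and TWIST1 at 0.11 (mean 0.07, camera adjusted p = 0.373). Among 12 housekeeping genes TFRC, the transferrin receptor, fell by 0.72 ± 0.10 and 11 did not pass (2 fell when adjusted over the list alone or without vehicle replicate 2); ACTB differed by −0.12 (adjusted p = 0.56) and GAPDH by −0.10 (adjusted p = 0.663). All 12 differences were negative, and the list's mean of −0.24 passed camera (adjusted p = 0.00309, or 0.35 with an estimated correlation). That mean lay between those of the ribosome biogenesis (−0.20) and fatty acid (−0.22) lists and those of the mitosis and amino acid lists (both −0.28).

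Markers of other cells were mostly dim, and host cells are mouse cells whose RNA can bind human probes in part. Among those named below, PTPRC and KRT10 were bright (12.96 each in vehicle tumours). Whether the signal of such markers comes from host or tumour cells was not tested. Of 14 fibroblast and pericyte markers POSTN, periostin, rose by 1.03 ± 0.14 (adjusted p = 0.00508) and CSPG4 fell by 0.92 ± 0.23 (adjusted p = 0.0441), 12 did not pass, the counts were the same when adjusted over the list alone, 2 rose without vehicle replicate 2, and the mean was 0.12 (camera adjusted p = 0.398). The call of CSPG4 ended without any array other than h10H5 replicates 1 and 2 (adjusted p up to 0.105) and with quantile normalization (−1.05, adjusted p = 0.0577). Without any 1 of the h10H5 arrays POSTN lay below the limit for dim signals and was not tested. Of 5 endothelial markers 0 passed, also when adjusted over the list alone, with CDH5 at 0.64 ± 0.21 (adjusted p = 0.0955; 0.75 and 0.0275 with array weights) and PECAM1 at 0.37 (mean 0.17, camera adjusted p = 0.439). Of 7 myeloid markers 0 passed, also when adjusted over the list alone (mean 0.09, camera adjusted p = 0.662), with AIF1 at 0.24 and PTPRC at −0.13; both other tested probe sets of PTPRC lay the other way at an unadjusted p under 0.05. The lists of neutrophil, red blood cell, skin, fat and lymphocyte markers had fewer than 5 tested members; PRF1 was at 0.32, HBB at 0.41, KRT10 and SFN at −0.26 and −0.15, CIDEC at 0.29, and CD79A and CD79B at 0.15 and −0.45, and none of them passed.

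Skeletal muscle markers were high in 2 of the h10H5 tumours. Relative to vehicle, the list's mean was 2.11 in h10H5 replicate 1 and 1.62 in replicate 3, against 0.49 and 0.17 in replicates 2 and 4 and a range from −0.81 to 0.55 in vehicle tumours. MYL11, a fast muscle myosin light chain, reached 11.1 and 10.9 in replicates 1 and 3 and at most 7.80 on the other arrays, and ACTA1, skeletal actin, reached 10.6 and 10.2. Not all members stood out in both. DES and ACTN3 lay above all vehicle arrays in replicate 1 (8.02 and 7.94). In replicate 3 they lay within the vehicle range (7.47 and 6.75). Of the 7 members 0 passed, also when adjusted over the list alone (MYL11 2.82 ± 0.97, adjusted p = 0.111; ACTA1 1.70 ± 0.70, adjusted p = 0.166), and the list's mean of 1.10 passed narrowly (camera adjusted p = 0.0466; adjusted p = 0.585 with an estimated correlation). It did not pass with quantile normalization (0.96, adjusted p = 0.141), with the mean of each gene's probe sets (1.08, adjusted p = 0.0537) or without vehicle replicate 1 or 2 or h10H5 replicate 1 or 3 (up to 0.376). It did pass with arrays centred on their medians (0.96, adjusted p = 0.00226), without h10H5 replicate 4 (1.41, adjusted p = 0.00728) and with array weights (1.70, adjusted p = 0.00252). With weights 3 members passed, among them MYL11 (4.05, adjusted p = 0.0185) and ACTA1 (2.64, adjusted p = 0.0267). Without h10H5 replicates 1 and 3, an alternative chosen after seeing the data, 182 genes were higher and 304 lower, and 304 of the 818 changed genes were among them. The fatty acid list then did not pass (−0.14, adjusted p = 0.0937) and the mitochondrial list did (−0.22, adjusted p = 4.41e-04).

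**Figure D3:**
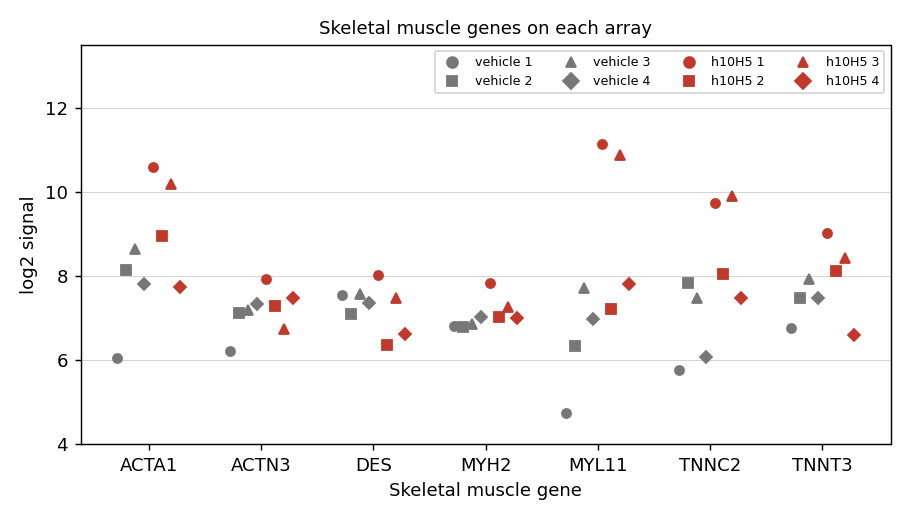
log2 signal of the 7 tested skeletal muscle markers on each array; grey symbols are vehicle tumours, red symbols are h10H5 tumours, and the symbol shape gives the replicate. MYL11 and TNNC2 stand above all other arrays in h10H5 replicates 1 and 3.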

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

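Within each group of 4 arrays, the array farthest from the rest was set against the group's range for the 26 lists, 97 named genes and 5 array measures. In 256 such groups 11 arrays stood apart, where chance alone gives about 1 in 20, or 12.8. The 11 were spread over 6 of the 8 arrays, with 3 in h10H5 replicate 4.

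In vehicle tumours, the noradrenergic list mean was 0.19 in replicate 3 against at most −0.04 in the other 3, and the endothelial list mean was −0.06 (−0.0636) in replicate 2 against at least 0.02. FADS2 was 10.5 in vehicle replicate 2 against at least 11.2, and GADD45A was 10.55 in vehicle replicate 4 against at least 10.77. In h10H5 tumours, the replication list mean was −1.01 in replicate 1 against at most −1.13, and the myeloid list mean was 0.40 in replicate 2 against at most 0.02. ALLC was 7.65 in h10H5 replicate 1 against at least 8.27, and PAIP2B was 9.13 in replicate 4 against at most 8.69. PSAT1 was 11.42 in h10H5 replicate 2 against at least 11.68. In h10H5 replicate 4, PTPRC was 12.04 against at least 13.00, and TEDC2 was 6.74 against at least 7.48.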

How the results depend on the processing

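The counts of splits, the runs without h10H5 replicates 1 and 3 together and the exact permutation of the arrays per list were chosen after seeing the data; the causes of the moves below were not tested unless named. Called genes kept their sign in nearly all settings (816 of 818 with the mean of a gene's probe sets, 604 of 621 without probe sets that mark shared probes, all 818 with median centring), while the number past the threshold moved. Centring on medians gave 45 higher probe sets, 51 higher genes and 50 at least 1.5-fold higher. Testing all probe sets, dim ones included, gave 59 higher and 150 lower probe sets, 126 higher and 242 lower genes and 87 at least 1.5-fold higher, and a stricter filter 614 and 814 probe sets, 718 lower genes and 85 at least 1.5-fold higher; the number tested moves with these filters. Trend and robust settings gave 557 and 745 probe sets and 750 lower genes, and array weights 907 and 959 probe sets and 786 and 878 genes. Without shared-probe names 145 and 222 probe sets and 254 and 318 genes were called among fewer tested, 507 of them among the 818. Leaving out 1 array, which also lowers the number of samples, gave from 31 to 203 higher and 90 to 364 lower probe sets, 94 to 297 higher and 183 to 490 lower genes, 79 to 154 at least 1.5-fold higher and 167 to 283 at least 1.5-fold lower, and 1 to 3 lists up and 8 to 11 down. Without h10H5 replicates 1 and 3, 20 and 86 probe sets, 182 and 304 genes and 1 list up were called; fatty acid synthesis then did not pass (−0.14, adjusted p = 0.0937) and mitochondrial respiration did (−0.22, adjusted p = 4.41e-04), and the skeletal muscle list then had a mean of 0.22 with camera's direction down (adjusted p = 0.971). Without shared-probe names IDI1 turned to 0.24 and N4BP2L1 went from 1.70 to 0.13, both from another probe set. Of the 66 named genes past the threshold, 34 stayed past it in all 8 fits that left out 1 array, 30 did not in at least 1, and 2 (POSTN and MRNIP-DT) lost no call but were too dim to be tested in some, and of the 12 lists, 9 did; ERK output, unfolded protein response and skeletal muscle did not. With an estimated correlation 0 lists passed up and 0 down, and by an exact permutation of the arrays 0 up and 0 down after adjustment (adjusted p = 0.0743 at best; 10 lists, 9 of them called, had the smallest p that 35 splits allow, 0.0286). The means of 8 lists changed sign under another scaling, none of them called. The replicate numbers showed no clear pairing of the tumours, though 4 arrays per group cannot exclude one. Same-numbered arrays deviated together with correlations of −0.02, −0.05, 0.10 and −0.13, and 2 of 8 arrays correlated best with their own number. A fit with the number as a block gave 0 higher and 8 lower probe sets, 56 and 160 genes, 55 and 158 at least 1.5-fold, and 1 list up. Of the 35 ways to split the 8 arrays into 2 groups of 4, the real one alone (1) gave as many as 660 probe sets, 818 genes or 437 genes of at least 1.5-fold, with 0 in any other split. Chance is unlikely for these counts but not excluded, since 35 splits allow no exact permutation p below 0.0286. Any other split also holds the difference between vehicle and h10H5 inside its groups, which can lower its counts. For the 12 lists, 5 splits gave as many and the highest other 13, so chance is not excluded for that count. No detection calls were used, and dim genes lie near the background, where the size of a change is less certain.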

Other observations

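The lists in this part, the comparisons of lists and the tests of the noncoding and histone genes were chosen after the values were seen, so their members are not independent evidence of a direction; the second muscle list was chosen after the values of the first were seen, but before its own. The adjusted p of the 6 lists covers 32 lists, these 6 and the 26 of the report, and does not correct for that choice. Nor does the adjusted p over 5 contrasts, where the noncoding and histone genes each enter both with and without matching on signal level. Of 27 genes of DNA repair by recombination and crosslink repair 12 fell and 0 rose, with a mean of −0.55 (camera adjusted p = 1.48e-09; adjusted p = 0.0792 with an estimated correlation). POLQ and RAD54L fell by 1.35 and 1.34, BRCA1, a scaffold of recombination, by 1.32 ± 0.11 (SE), EXO1 by 1.19 and FANCI by 1.08. Of 18 centromere protein genes 9 fell (mean −0.56, camera adjusted p = 1.55e-07; adjusted p = 0.0437 with an estimated correlation), with CENPO at −1.18 and CENPW at −0.93 after CENPM, and 3 of the 18 also stand on the mitosis list. Among 10 genes of the E2F family and its partners 6 fell (mean −0.62, camera adjusted p = 1.51e-04; adjusted p = 0.175 with an estimated correlation), both activators (E2F1 −1.24, E2F2 −1.47) and repressors (E2F7 −1.47, E2F8 −1.06). The mean of the replication list lay below that of the mitosis list by 0.83 relative to vehicle (−0.83, exact permutation p = 0.0286, two-sided, the smallest that 35 splits allow; exact permutation adjusted p = 0.0357 over 5 contrasts).

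Of 18 genes of purine and pyrimidine synthesis 9 fell and 0 rose (mean −0.29, camera adjusted p = 6.05e-05; adjusted p = 0.236 with an estimated correlation), among them CTPS1 at −0.62, CAD at −0.61 and PPAT, the committed step of purine synthesis, at −0.46. Of 28 nuclear pore genes 8 fell and 0 rose (mean −0.28, camera adjusted p = 3.91e-07; adjusted p = 0.0531 with an estimated correlation), led by NUP210 at −0.77 and NUP85 at −0.73. In the MYC network, of 11 genes 4 rose and 0 fell (mean 0.31, camera adjusted p = 0.00399; adjusted p = 0.236 with an estimated correlation): MYCN and MYC by 1.00 and 0.73, and the antagonists MXD1 and MXI1 by 0.60 and 0.57; with arrays centred on their medians 1 of the 4 passed. Of these 11 genes 3 (MYC, MYCN and MXI1) also stand on the fixed ERK, noradrenergic and hypoxia lists, where their calls were already given. Likewise E2F1 and E2F2 of the E2F list stand on the replication list, and MTHFD2 of the purine and pyrimidine list on the amino acid list. With centring 5 nuclear pore genes and 6 of purine and pyrimidine synthesis passed as lower.

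Skeletal muscle genes were high in h10H5 replicates 1 and 3, the 2 of 4 h10H5 arrays whose list mean lay above the highest vehicle array (0.55). Array means of a second list of 33 muscle genes, most of them dim (9 above the limit for dim signals), correlated with those of the first over the 8 arrays (Pearson r = 0.966, exact permutation p = 0.00109; Spearman rho = 0.857, exact permutation p = 0.0107; r = 0.919 without the 2 arrays farthest from the median), while 1 in 40 of 10000 random lists matched on level exceeded 0.58. PYGM lay 4.18 and 4.64 and ATP2A1 3.46 and 3.42 above vehicle in replicates 1 and 3, while NEB (−0.22 and 0.21) and TTN (0.01 and 0.23), also abundant in muscle, did not stand out, genes picked after their values were seen. Muscle tissue from the host in the tumour pieces is a candidate explanation that passed this test and was not excluded; whether the signal is of mouse or human RNA, and whether h10H5 raised it in some tumours, stays open and was not tested.

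Long noncoding RNA genes were more often higher than lower: of 676 tested 33 rose and 3 fell (LOC100506730, SLC20A1-DT and TMPO-AS1), against 298 and 470 of 11431 protein-coding genes. Dim signals, the scaling and the RNA of h10H5 replicate 4, the array with the highest ACTB but not GAPDH ratio of 3' to 5' probe sets, were each set against protein-coding genes matched on level. Against 10000 random lists of such genes the noncoding genes stood out: 1 in 40 lists had more than 26 higher genes, and the median gap of 0.095 (0.091 under quantile normalization, 0.087 without h10H5 replicate 4) exceeded the 0.03 that 1 in 40 lists exceed. Over the arrays the mean gap to matched genes did not pass: it was 0.12 (exact permutation p = 0.0571, two-sided, against a smallest possible 0.0286), 0.13 under quantile normalization and 0.09 without h10H5 replicate 4, with the same exact p, while the gap to all protein-coding genes, not matched on level, was 0.20 (exact permutation p = 0.0286; exact permutation adjusted p = 0.0357 over 5 contrasts). With quantile normalization 29 passed as higher and 3 as lower and with arrays centred on their medians 9 and 3, so the number of calls moved with centring, and the 3 explanations and an effect of h10H5 stay open because the matched gap does not exceed the spread between arrays.

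Histone genes of the replication-dependent clusters were mostly higher while replication genes were lower: of 20 tested 6 rose (H2AC6, H2AC25, H2BC9, H2BC21, H2BC5 and H2BC6) and 0 fell. The differences of 17 were positive, while H4C11 (−0.66, adjusted p = 0.0648), H2AC8 (−0.37) and H2AC14 (−0.33) lay the other way without passing. The median was 0.44 and the mean gap to other genes matched on level 0.30 (exact permutation p = 0.0286, two-sided, the smallest possible, and exact permutation adjusted p = 0.0357 over 5 contrasts). Centring moves all genes of an array alike, so it could not change the gap to matched genes. With arrays centred on their medians the median was 0.30, with 2 genes passing as higher and 1 as lower. Quantile normalization could change that gap. Under it the median was 0.37, above the 0.16 that 1 in 40 random lists matched on level exceed, and 7 genes rose and 0 fell. The mean gap under it was 0.30 (exact permutation p = 0.0286). These values argue against scaling as the whole cause, though the number of calls moved with centring. Probes shared between the near-identical copies stay open: over the 12 genes with probe sets whose names mark no shared probes the median was 0.26, short of the 0.31 that 1 in 40 random lists exceed, 1 rose, and the mean gap was 0.24 (exact permutation p = 0.0857). Longer polyadenylated transcripts, which this labelling would favour, could raise the signal without more histone RNA; SLBP, which binds the end of the unpolyadenylated form, fell by 0.84 ± 0.10 (SE; adjusted p = 0.00327), but no probe positions are given, so the explanations cannot be told apart.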
